A study of Mus musculus with 4 samples.

How the data were processed

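White adipose tissue RNA from female C57BL/6 mice on a high fat diet (HFD) or a low fat diet (LFD) was measured on 4 one-colour arrays, 2 per diet, all on 1 slide and in 1 scan, per the file headers. Each sample received 500 ng of labelled RNA, per the labels. The spot brightness values are linear intensities that the authors deposited as scanner output. Background was subtracted and signals were detrended within each array by Feature Extraction, per the file headers, without normalisation between arrays. The submitters' processing notes give Feature Extraction 11.5.1.1 and the headers 11.0.1.1. The deposited value table holds the ratio of each spot's processed signal to the 75th percentile of its array, found by dividing the scanner signals by it. Its column medians were 0.117, 0.127, 0.130 and 0.131; it is linear and uncentred, and runs in the direction of signal.

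Each array held 45018 spots, of which 43379 were not controls and made up 41174 probes. Spots of 1 probe were averaged and spots flagged as outliers by Feature Extraction (60 to 115 per array) were left out. No spot was saturated. Log2 of the processed signal minus the array's 75th percentile was analysed. Probe names were updated through transcript accessions in a RefSeq gene table of another mouse build, which was used for names only: 27668 probes matched, 13506 kept the file's name and 1843 changed symbol. Probe coordinates are those of the files, in build mm9, and no gene annotation of that build was used here. A gene was represented by its tested probe with the highest mean signal. Of 5984 genes with more than 1 tested probe, 1855 had probes of opposite sign.

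Probes well above background on both arrays of at least 1 diet were tested, 26054 in all, for 17736 genes. HFD was compared with LFD in limma 3.58.1 (lmFit and eBayes, two-sided, R 4.3.3, data.table version 1.17.8), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior of 2.24. Gene lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over all 40 lists, and again with an estimated correlation and with fry. For a probe not well above background on either array of a diet, the fold is a lower bound under this background handling only. It sets the mean of the brighter diet against the mean of, per array, the higher of the dim probe's signal and the lowest signal well above background. Such a bound is not strict, as normexp gave smaller changes for some of these genes. The number of arrays limits the precision.

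Named genes followed a rule fixed before the data were examined. They were the 10 largest rises and 10 largest falls past the threshold with non-overlapping diets and a probe well above background on both arrays of the higher diet, up to 4 genes of smallest p per list, and a fixed panel. Uncharacterised transcripts and immunoglobulin or T cell receptor segments were passed over. Pck1, in the panel, was not analysed here. Some genes that the rule names are not reported here. Every gene called higher or lower by name had both HFD arrays on the same side of both LFD arrays.

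The procedure was tested on simulated data for the comparison of HFD with LFD over 17736 genes. With 200 genes changed, 28%, 82%, 88% and 90% of those changed 2-, 4-, 8- and 16-fold were recovered. With 2014 changed, 81.5%, 96.1%, 98.6% and 99.4% were. Genes that had not been changed made up 12 calls in the former and 103 of 1991 calls in the latter simulation. Simulated genes varied independently, with variances drawn from the fitted prior and no background floor, so recovery in the real data may be lower. Alternatives were normexp with an offset of 50, quantile and median scaling, the deposited value table, other filters on dim probes, flagged spots kept, the mean of a gene's probes, eBayes with trend and robust options, the replicate number as a block, each array left out, all probes counted, a 2-fold minimum, a threshold of 0.10, and camera without genes shared by lists. The slide as a block was not run because all arrays shared 1 slide. Lists of urothelium, mammary and neuron genes and gene families were added after seeing the data.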

Results

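White adipose tissue of female C57BL/6 mice, a common inbred laboratory strain, was profiled after a high fat diet (HFD) or a low fat diet (LFD). The diets began at 8 weeks of age and lasted 18 weeks, and the series text gives diet-induced obesity as the model. RNA was hybridised to 1-colour whole mouse genome arrays, on which each spot's brightness stands for the level of 1 transcript, with 2 arrays per diet. The sources used here name no fat depot. They describe each sample as tissue mixed from 3 mice, and leave open whether the 2 replicates of a diet came from separate pools or from the same pool. The p-values therefore measure only the spread between these samples, which may be technical. Probes well above background numbered 26420 and 27937 on the LFD arrays, and 27251 and 21312 on the HFD arrays. The last of these, HFD replicate 2, also had the strongest signal at negative control spots, 109.5 against 63.5 to 97.0 on the other arrays. Over the 26054 tested probes, log2 signals correlated across probes with r = 0.989 between the LFD arrays and r = 0.992 between the HFD arrays. Between diets r was 0.965 to 0.971; probes are not independent replicates.

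The comparison asked which transcripts differed in fat between mice fed HFD and mice fed LFD. Genes of macrophages and of inflammation were higher in HFD, among them Saa3 (18.8-fold), Ccl2 (14.8-fold), Cd68 (4.87-fold) and Trem2 (7.70-fold). Genes of fatty acid synthesis, mitochondrial metabolism and brown fat, and markers of mesothelium, were lower, among them Ucp1 (32.3-fold), Krt7 (4.72-fold), Acaca (7.28-fold) and Acacb (6.41-fold). These list calls came from camera with a preset correlation, and none held with an estimated one (adjusted p of at least 0.665 with an estimated correlation). Estimated correlations were 0.699 for oxidative phosphorylation, 0.659 for the cell cycle, 0.638 for mesothelium and 0.372 for macrophages. These lie far above the preset of 0.01, so the preset p-values of such lists are likely too small. The citric acid cycle and neutrophil lists, with estimated correlations of only 0.030 and -0.170, also had 0.665 with an estimated correlation. Camera with an estimated correlation also has only the 2 residual degrees of freedom of the fit, so a list could hardly pass. Loss of a call in that setting therefore does not by itself show correlated genes or an unchanged list. In fry 7 of the 16 called lists passed, those of macrophages, lipid-associated macrophages, inflammatory genes, neutrophils, mesothelium, the citric acid cycle and branched-chain amino acid breakdown. The other 9 lost their call there, with adjusted p of 0.0654 for extracellular matrix, 0.0662 for oxidative phosphorylation, 0.0702 for immediate early genes, 0.0889 for brown and beige fat, 0.0992 for fatty acid synthesis, 0.128 for the cell cycle, 0.129 for MHC class II, 0.140 for fatty acid oxidation and 0.170 for endoplasmic reticulum stress. Gene lists for pathways and cell types were fixed before the data were examined. With limma, 1019 of 17736 genes were higher and 995 were lower in HFD at an adjusted p under 0.05, and 496 of the former and 472 of the latter changed at least 2-fold. For 68.9% of genes both HFD arrays lay on the same side of both LFD arrays, against 33.3% expected by chance. These counts depended on the arrays used: 427 genes were higher and 264 lower without LFD replicate 1, 471 and 338 without LFD replicate 2, 10 and 9 without HFD replicate 1, and 9 and 9 without HFD replicate 2. With no filter on dim probes 0 genes passed in either direction with limma, although 5608 had an unadjusted p under 0.05, against 6188 with the filter.

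**Figure D1:**
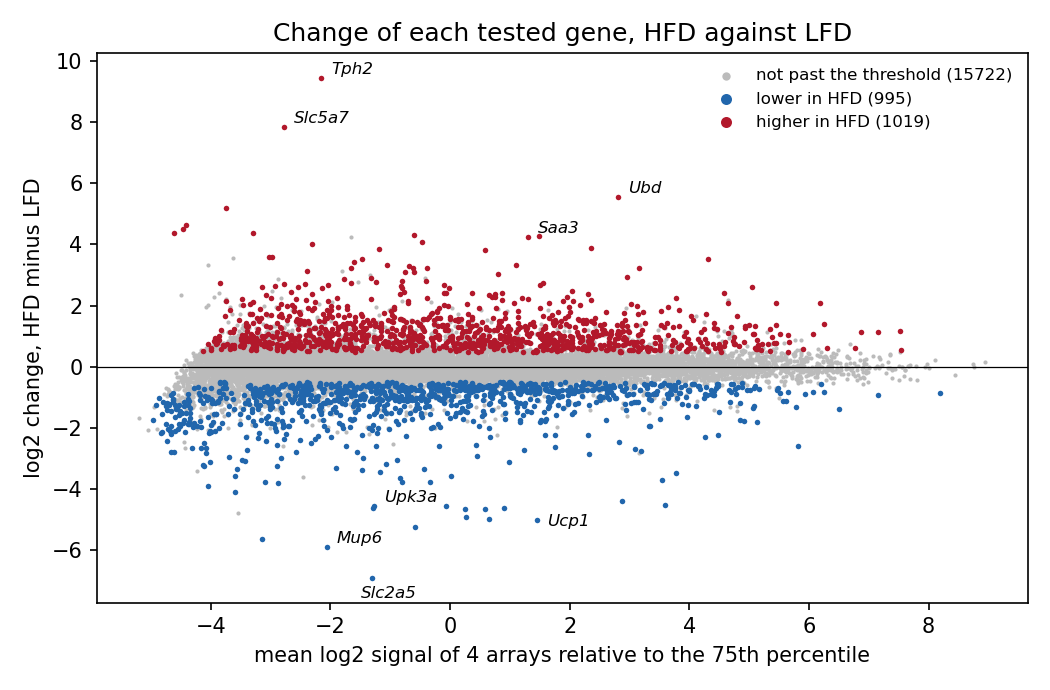
Log2 change of each of 17736 tested genes, HFD minus LFD, against its mean log2 signal over 4 arrays relative to each array's 75th percentile. Each point is a gene, with the 1019 genes higher in HFD in red, the 995 lower in blue and the others in grey; Tph2 and Slc5a7 lie highest and Slc2a5 lowest, drawn at measured values although their folds are lower bounds.

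The largest rise belonged to Tph2, which encodes a rate-limiting enzyme of serotonin synthesis best known from neurons. Its probe, which lies at chromosome 10, positions 114516101 to 114516160 of the mouse build mm9, was not well above background on either LFD array. The log2 signal relative to the array's 75th percentile was 2.57 ± 0.27 (SD, n = 2) in HFD and -6.87 ± 0.07 (SD, n = 2) in LFD, a difference of at least 141-fold (adjusted p = 0.0040). Slc5a7, the high-affinity choline transporter, was at least 52.5-fold higher (adjusted p = 0.0099). The same kind of lower bound held for Dppa3, a gene of early embryos and germ cells (at least 11.1-fold), Il13ra2, a receptor for interleukin 13 (at least 10.8-fold), and Pvalb, a calcium-binding protein of fast muscle (at least 5.57-fold). It also held for Cxcl1, a chemokine that attracts neutrophils (at least 5.15-fold), and Olr1, a receptor for oxidised lipoproteins (at least 4.46-fold). These 5 genes had adjusted p between 0.0040 and 0.0142. The sizes depended on the background handling: with normexp and an offset of 50 the log2 change was 5.79 for Tph2, 4.45 for Slc5a7, 2.18 for Dppa3, 2.38 for Il13ra2, 1.61 for Pvalb, 1.63 for Cxcl1 and 1.65 for Olr1, and all 7 kept their call. Each of these changes was smaller than the bound given above, so the bounds hold only under the main background handling. Genes measured in both diets that rose most were Ubd, a ubiquitin-like protein induced by cytokines, at 46.6-fold (log2 change 5.54, SE 0.41, adjusted p = 0.0147), the secreted phospholipase Pla2g5 at 19.7-fold and the matrix protein Crtac1 at 19.4-fold, with a log2 change of 3.57 for the mean of the Crtac1 probes and of 3.53 for Pla2g5 with normexp.

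The largest fall was that of Slc2a5, a fructose transporter, which was not well above background on either HFD array. Its log2 signal was 2.14 ± 1.47 (SD, n = 2) in LFD and -4.76 ± 0.38 (SD, n = 2) in HFD, a difference of at least 60.4-fold (adjusted p = 0.0218). Sptssb, a small subunit of the enzyme that starts sphingolipid synthesis, was at least 11-fold lower in HFD. Mup6 was at least 25.2-fold and Mup8 24.7-fold lower, but the genes of the major urinary proteins are near-identical copies whose transcripts can share a probe, so the values cannot be assigned to single genes. Ucp1, the uncoupling protein of brown and beige fat, was 32.3-fold lower with a wide spread in LFD, from 5.10 on replicate 1 to 2.82 on replicate 2 on the log2 scale (adjusted p = 0.0371, and 0.0510 with the trend and robust options). The acyl-CoA synthetase Acsm3 was 31.8-fold and the cytochrome P450 gene Cyp2f2 25-fold lower. Falls of 37.5-fold for Wfdc2, a protein secreted by epithelia, 24.5-fold for the water and glycerol channel Aqp3 and 23.7-fold for Upk3a, a membrane protein of the bladder lining, rested on signals well above background on 1 of 2 HFD arrays. With normexp the log2 changes were -4.67 for Slc2a5, -2.86 for Sptssb, -3.73 for Mup6, -3.99 for Wfdc2, -3.06 for Aqp3, -3.16 for Upk3a and -4.01 for Cyp2f2, and these calls also held. The falls of Slc2a5, Sptssb and Mup6 were then smaller than their bounds. Without LFD replicate 1 and without LFD replicate 2 the log2 change was -7.93 and -5.86 for Slc2a5, and -3.87 and -6.15 for Ucp1.

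Markers of macrophages and monocytes rose together: 19 of 24 measured genes were higher in HFD and none lower, with a median log2 change of 1.31. Adjusted over the list alone, 23 were higher. Itgax, which encodes CD11c, rose 8.24-fold (log2 change 3.04, SE 0.11, adjusted p = 0.0101), but its dimmer probe went the other way and the mean of its probes did not pass (log2 change 1.05, adjusted p = 0.256). Cd68 rose 4.87-fold, Tyrobp 3.29-fold and Adgre1, a surface receptor of mature macrophages, 3.13-fold. The list passed camera (adjusted p = 2.9e-13), and not when the correlation between its genes was estimated from the data (adjusted p = 0.665 with an estimated correlation). Lipid-associated macrophage and lysosome genes had a median of 0.66, with 10 of 23 higher, 15 adjusted over the list alone, where 1 was lower; without LFD replicate 2 the median was 1.05. They were led by Trem2 (log2 change 2.95, SE 0.17), Ctss, a lysosomal protease (4.2-fold), Spp1, which encodes osteopontin (9.80-fold), and Gpnmb (9.96-fold; camera adjusted p = 2.1e-06, and 0.665 with an estimated correlation). Among inflammatory cytokines and chemokines, 11 of 23 genes were higher and 1, the B cell chemokine Cxcl13, was lower, with a median of 1.31 (14 higher and 2 lower adjusted over the list alone). The acute-phase protein Saa3 rose 18.8-fold, the interleukin 1 antagonist Il1rn at least 16.3-fold, the monocyte chemokine Ccl2 14.8-fold, Ccl3 4.51-fold and Tnf 2.48-fold. With normexp the log2 change was 2.41 for Il1rn, which is smaller than its bound, 1.28 for Ccl3 and 2.66 for Spp1. This list of cytokines had a camera adjusted p of 7.9e-06, and an adjusted p of 0.665 with an estimated correlation. Il6 was below the filter and was not tested.

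Genes of alternatively activated and resident macrophages went both ways and did not pass as a list (median 0.29, mean 0.05, camera adjusted p = 0.881), and fry gave them the opposite, downward sign. Of 14 measured genes 2 were higher, Clec10a among them, and 4 lower, with 4 and 5 adjusted over the list alone. The scavenger receptor Cd163 fell 1.89-fold, Timd4 3.25-fold with a signal well above background on 1 of 2 HFD arrays (log2 change -0.74 with normexp), Lyve1 1.78-fold and Ccl24 1.63-fold. Mrc1 had a log2 change of 0.38 (SE 0.09, adjusted p = 0.0718).

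Antigen presentation by MHC class II was higher as a list, with a median of 1.01 and 3 of 10 genes higher, H2-DMb1 (3.56-fold), H2-Aa (2.58-fold) and Cd86 (1.46-fold); adjusted over the list alone there were 8. Its camera adjusted p was 0.000756, and its adjusted p = 0.665 with an estimated correlation. Neutrophil genes had 2 of 6 members higher, S100a8 (11.4-fold; log2 change 2.57 with normexp) and Csf3r (1.86-fold), and 3 adjusted over the list alone (median 0.69, camera adjusted p = 0.0059, and 0.665 with an estimated correlation). The neutrophil median ranged from 0.44 to 0.75 over 16 alternative settings. Cell cycle genes had a median of 1.08 with 6 of 29 higher, among them Ube2c (2.12-fold), Ccne1 (1.99-fold) and Aurka (1.99-fold), and 17 adjusted over the list alone. The median was 0.59 without LFD replicate 2. The camera adjusted p was 2.0e-07, and the adjusted p = 0.679 with an estimated correlation. Extracellular matrix genes had 13 of 38 higher and 2 lower, with 17 and 3 adjusted over the list alone (median 0.47, camera adjusted p = 7.3e-05, and 0.665 with an estimated correlation). Col6a2 rose 2.36-fold, the basement membrane collagens Col4a2 2.20-fold and Col4a1 1.99-fold, Sparc 2.08-fold and the protease inhibitor Timp1 4.80-fold, whereas Col6a3 had a log2 change of 0.94 (SE 0.18, adjusted p = 0.0513).

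Immediate early genes and endoplasmic reticulum stress genes passed camera with small medians of 0.23 and 0.18 (adjusted p = 0.0347 for each). With an estimated correlation the adjusted p was 0.665 and 0.762. The former had 4 of 18 genes higher, Atf3 (4.71-fold), Egr2 (4.90-fold), Junb (2.27-fold) and Btg2 (1.44-fold; adjusted p = 0.0529 with the mean of its probes), with 8 higher and 1 lower adjusted over the list alone. The latter had 1 of 21, also when adjusted over the list alone, and that was the stress-induced transcription factor Atf3 again. The call for stress genes was lost in 9 of 17 alternative settings and that for immediate early genes in 8 of 17. Neither held without LFD replicate 2 (adjusted p = 0.244 and 0.394), and the call for stress genes was also lost without HFD replicate 2 (0.0704) and that for immediate early genes without HFD replicate 1 (0.0574). The median of immediate early genes was 0.37 without LFD replicate 1 and 0.42 without HFD replicate 2.

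**Figure D2:**
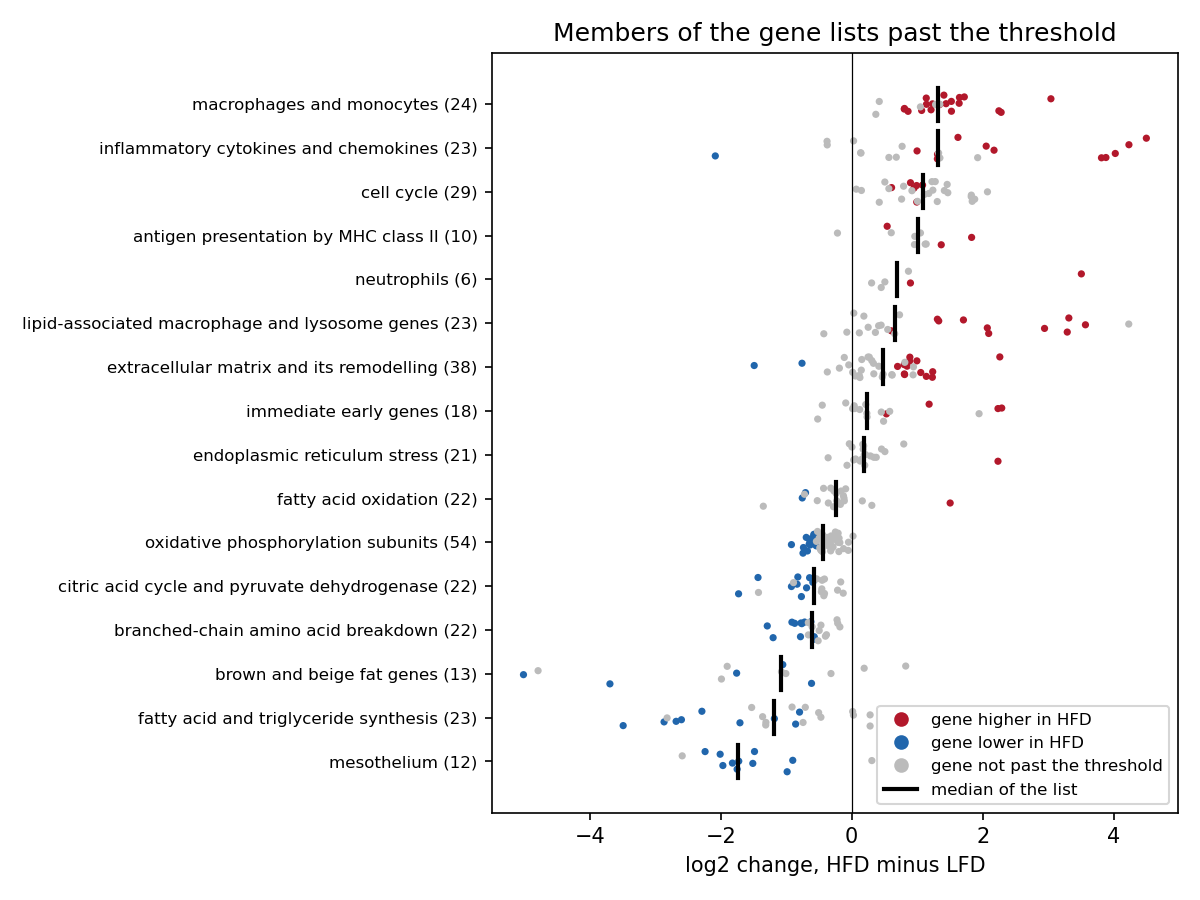
Log2 change, HFD minus LFD, of the members of the 16 gene lists that passed camera, with the number of measured genes in parentheses. Each point is a gene, red where higher, blue where lower and grey where not past the threshold, and black bars are medians, from 1.31 for macrophages and monocytes to -1.74 for mesothelium; vertical scatter within a row only separates points.

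Genes of fatty acid and triglyceride synthesis were lower in HFD, with 9 of 23 lower and none higher, 18 when adjusted over the list alone, and a median of -1.18. The acetyl-CoA carboxylases Acaca (7.28-fold) and Acacb (6.41-fold), which make malonyl-CoA, were among these, with Mogat1 (4.88-fold) and the desaturase Fads1 (2.27-fold). Fasn fell 1.81-fold (log2 change -0.86, SE 0.13, adjusted p = 0.0345), a call lost with quantile normalisation (0.0628). With the mean of each gene's probes the log2 change was -2.20 for Acaca, -1.91 for Acacb and -1.43 for Fasn. Scd1 had a log2 change of 0.02 (SE 0.09, adjusted p = 0.920) and Srebf1 one of -0.71 (SE 0.23, adjusted p = 0.120). The list had a camera adjusted p of 4.4e-07, and an adjusted p of 0.665 with an estimated correlation.

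Mitochondrial lists moved in the same direction by smaller amounts. Among oxidative phosphorylation subunits 14 of 54 were lower and none higher, with a median of -0.43 and 34 lower when adjusted over the list alone. Sdha, a subunit of succinate dehydrogenase, fell 1.89-fold, the complex III subunits Uqcrc2 and Uqcrb 1.67-fold each and the complex I subunit Ndufa10 1.57-fold. For the citric acid cycle and pyruvate dehydrogenase 10 of 22 genes were lower (median -0.58), including the kinase Pdk1, an inhibitor of pyruvate dehydrogenase (3.31-fold), and Pdha1, a subunit of that enzyme (2.69-fold). For branched-chain amino acid breakdown 11 of 22 were lower (median -0.61), including Acadsb (2.44-fold), Aldh6a1 (2.30-fold) and Hibch (1.71-fold). Each of the latter lists had 19 lower genes adjusted over the list alone. The camera adjusted p of these lists was 2.9e-13, 3.1e-09 and 1.6e-09, and each had an adjusted p of 0.665 with an estimated correlation. Fatty acid oxidation had a median of -0.23 with Acadvl (1.63-fold) and Pex11a (1.69-fold) lower and Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation, 2.84-fold higher; adjusted over the list alone 5 were lower and 1 higher. Its camera adjusted p was 0.0059, and its adjusted p = 0.724 with an estimated correlation; without LFD replicate 1 the median was -0.14 and the camera adjusted p 0.0874.

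Brown and beige fat genes had 5 of 13 lower, 6 adjusted over the list alone, and a median of -1.07, which is -1.06 with 3 genes that were dim in 1 diet set to their bound, and -1.74 without LFD replicate 2. Besides Ucp1, Cidea fell 12.9-fold, Dio2 3.38-fold with a signal well above background on 1 of 2 HFD arrays (log2 change -0.93 with normexp), and the coactivator Ppargc1a 2.07-fold (log2 change -1.05, SE 0.09, adjusted p = 0.0172). The camera adjusted p was 0.0015, and the adjusted p = 0.665 with an estimated correlation. Insulin signalling did not pass (median -0.25, camera adjusted p = 0.0508), with 5 of 20 lower and 1 higher, or 10 and 2 adjusted over the list alone. It passed as lower in 7 of 17 alternative settings, among them fry (adjusted p = 0.0340), normexp (0.00459), without LFD replicate 2 (0.0401) and without HFD replicate 1 (0.0352), over a range of adjusted p from 0.00139 to 0.665. Its median was -0.15 without LFD replicate 1. Irs1, an insulin receptor substrate, fell 2.60-fold, the regulatory subunit Pik3r1 2.46-fold and Pdpk1 1.62-fold, with probes of opposite sign for the last, and the calls for Pik3r1 and Pdpk1 were lost with the mean of each gene's probes (adjusted p = 0.0506 and 0.210). Without LFD replicate 1 the log2 change of Pdpk1 was -0.11, but from another of its probes, as the brightest probe was chosen anew in each setting. Grb14, an adaptor that binds the insulin receptor, rose 1.98-fold. Slc2a4, the insulin-responsive glucose transporter, had a log2 change of -1.28 (SE 0.27, adjusted p = 0.0581).

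Mesothelium markers were lower in 10 of 12 genes, and in 11 adjusted over the list alone, with a median of -1.74 (camera adjusted p = 3.3e-07, and 0.665 with an estimated correlation). Krt7 fell 4.72-fold, Upk3b 3.36-fold, Muc16 3.30-fold and Wt1 2.80-fold. The list of mammary and other epithelium had 7 of 15 lower and 1 higher, the same numbers when adjusted over the list alone, and did not pass (adjusted p = 0.133). Its median of 0.10 and its mean of -0.91 differed in sign, with Krt5 10.8-fold, Krt18 6.58-fold, Krt8 3.98-fold and Cdh1 at least 2.92-fold lower. With normexp the log2 change was -2.59 for Krt5 and -0.99 for Cdh1, the latter a smaller fall than its bound. It passed as lower with the mean of each gene's probes (adjusted p = 0.0489), without the filter on dim probes (0.0463), without LFD replicate 1 (0.0407), without HFD replicate 2 (0.0240) and in fry (0.0409). Markers of mesothelium (median -1.74) and macrophages (median 1.31) thus moved with diet beside the metabolic lists, whereas those of endothelial cells (median 0.09) and adipocytes (median -0.01) did not pass.

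Adipocyte identity genes had a median of -0.01 with 1 of 18 lower, Acvr1c (1.51-fold; adjusted p = 0.0563 with the mean of its probes), and 3 higher and 3 lower adjusted over the list alone (adjusted p = 0.588). Log2 changes were -0.32 for Adipoq (SE 0.10, adjusted p = 0.119), -0.43 for Cfd (SE 0.11, adjusted p = 0.0821), -0.27 for Pparg (SE 0.22, adjusted p = 0.426) and -0.14 for Lipe (SE 0.17, adjusted p = 0.571), whose probes differed in sign. Adipokines and fat expansion genes split into 3 of 16 higher and 3 lower, 7 and 7 adjusted over the list alone (median 0.24, camera adjusted p = 0.881), with an upward sign in camera and a downward one in fry. Mest, an imprinted gene linked to adipocyte enlargement, rose 11.4-fold (log2 change 3.51, SE 0.32, adjusted p = 0.0181). Agt, the angiotensin precursor, fell 3.83-fold, Retn, which encodes resistin, 1.87-fold and Nampt 1.70-fold. Lep, which encodes leptin, had a log2 change of 2.18 (SE 0.53, adjusted p = 0.0729), Sfrp5 one of 3.01 (SE 0.61, adjusted p = 0.0554) and Npr3 one of 1.46 (SE 0.40, adjusted p = 0.0905), each with an SD between LFD arrays of at least 0.81. Over 14 alternative settings these ranged from 1.43 to 2.93 for Lep, 2.13 to 3.89 for Sfrp5 and 0.89 to 2.03 for Npr3. Each of these genes passed as higher in some of those settings.

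**Figure D3:**
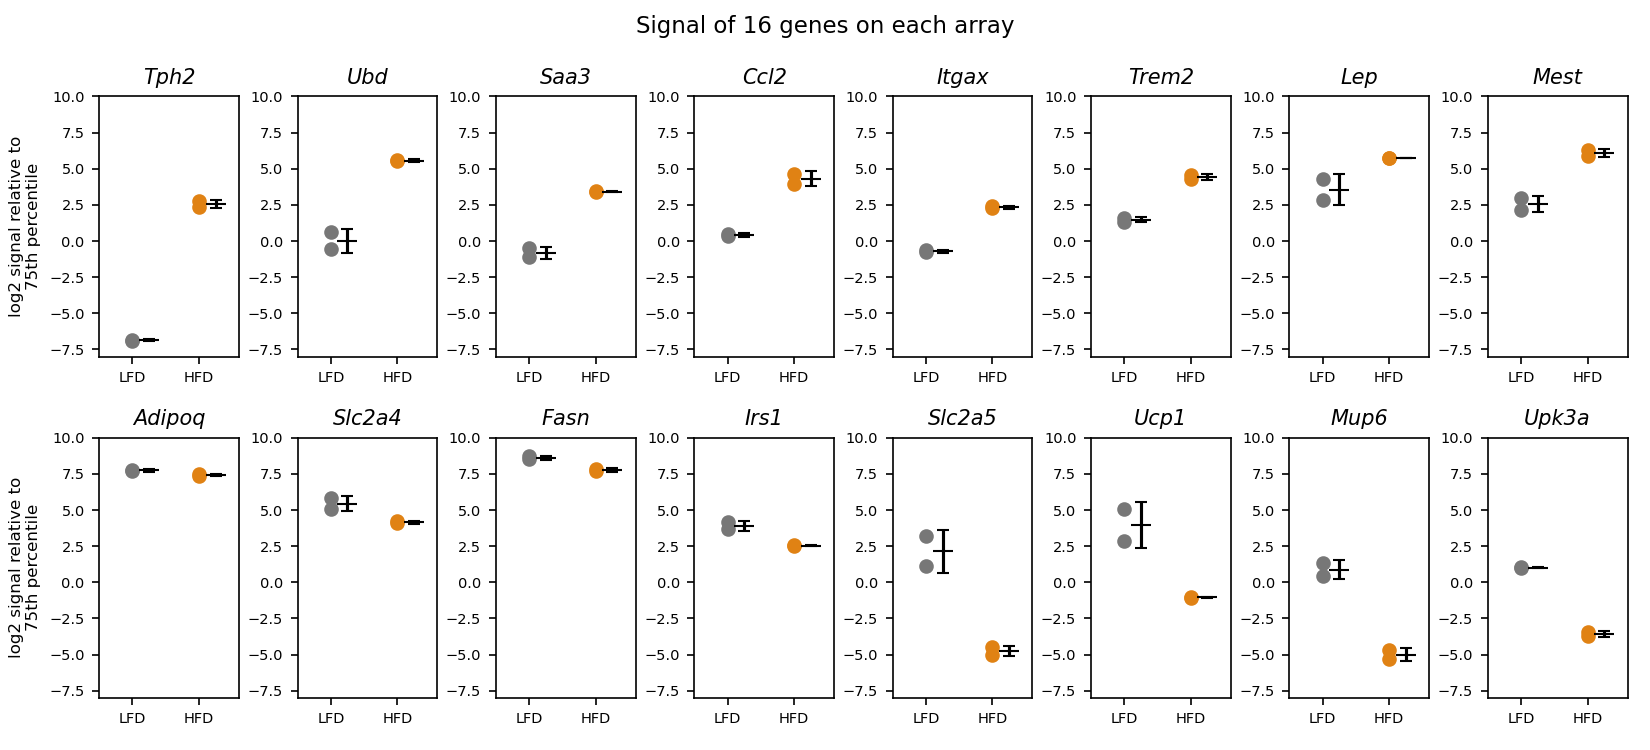
Log2 signal relative to the array's 75th percentile for 16 genes on each of 4 arrays, LFD in grey and HFD in orange, with the mean and SD (n = 2) of each diet as black bars beside the points. Tph2 lies at -6.87 in LFD and 2.57 in HFD on average, and Ucp1 at 3.96 and -1.05, with the LFD arrays far apart for Ucp1 and Lep.

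The other pathway lists did not pass. Lipolysis had a median of -0.17 and a mean of 0.00 (adjusted p = 0.629), with Ffar2 (2.49-fold), Adora1 (2.00-fold) and Adcy5 (1.88-fold) higher and the lactate receptor Hcar1 (2.08-fold) lower; adjusted over the list alone 5 were higher and 6 lower. Adrb3 had a log2 change of -0.81 (SE 0.17, adjusted p = 0.0573). Cholesterol synthesis had a median of 0.04 (adjusted p = 0.881) with 2 of 24 genes higher and 1 lower, among them Hmgcs1 higher, with probes of opposite sign and no call for their mean (adjusted p = 0.123), and Fdft1 lower, and the same counts when adjusted over the list alone. The hypoxia list had a median of 0.01 and a mean of -0.17 (adjusted p = 0.637), with Egln3 (3.74-fold), Pdk1 (3.31-fold) and Vegfa (2.21-fold) lower, the same 3 when adjusted over the list alone. Antioxidant defence had a median of -0.05 (adjusted p = 0.259), with Gsta4 (6.04-fold) and Gpx3 (3.83-fold) among 4 lower genes and Hmox1 (2.67-fold) and Sod3 (2.11-fold) higher; adjusted over the list alone 2 were higher and 6 lower. It passed as lower without the filter on dim probes (adjusted p = 0.0203). The circadian clock list had a median of -0.18 (adjusted p = 0.176) with 1 of 17 genes lower, also when adjusted over the list alone; without HFD replicate 1 the median was -0.36 (adjusted p = 0.00579), and without the filter the list passed too (0.00969). In the interferon response list, with a median of 0.01 (adjusted p = 0.881), 0 of 23 genes passed in limma, also when adjusted over the list alone, and 2 had an unadjusted p under 0.05.

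Markers of other cell types did not pass as lists. Endothelial cells had a median of 0.09 (adjusted p = 0.656) with 1 of 19 lower, Lyve1. Preadipocytes and fibroblasts had a median of -0.15 (adjusted p = 0.238), with Dlk1 (2.71-fold), Dpp4 (1.77-fold) and Pdgfra (1.63-fold) among 5 lower genes and Zfp423 (1.75-fold) higher. Smooth muscle and pericytes had a median of -0.03 (adjusted p = 0.656) and mast cells one of -0.17 (adjusted p = 0.629), with no gene past the threshold in limma; 0 of 11 and 2 of 7 genes had an unadjusted p under 0.05. T and NK cells had a median of 0.18 (adjusted p = 0.541), with 1 of 19 genes higher, Klrb1c, and 1 lower. B and plasma cells had a median of -0.37 against an upward camera sign (adjusted p = 0.742), with Blnk and Ighm higher; without LFD replicate 1 the median was 0.43 (adjusted p = 0.0143). Dendritic cells had a median near 0 (adjusted p = 0.742), with Ccl17 (3.34-fold), Batf3 (2.15-fold) and Irf8 (2.12-fold) higher and Siglech at least 1.42-fold lower. Schwann cells and nerve had a median of -0.42 (adjusted p = 0.180) with 3 of 10 genes lower, among them Mal and Prx, each well above background on 1 of 2 HFD arrays. Skeletal muscle had a median of 0.36 (adjusted p = 0.251) with Pvalb higher and Myl1 lower, and pancreas one of 0.36 (adjusted p = 0.133) with Cela1 5.22-fold higher. Liver had a median of -0.31 (adjusted p = 0.371) with Cyp2e1 4.67-fold lower, ovary and uterus one of -0.23 (adjusted p = 0.371) with the estrogen receptor Esr1 2.26-fold lower, and keratinocytes and skin one of 0.16 (adjusted p = 0.881) with Ivl lower and not well above background on either HFD array, and Serpinb2 1.46-fold higher with a signal well above background on 1 of 2 HFD arrays. Adjusted over the list alone, these 13 lists gave the same counts except for preadipocytes (2 higher), dendritic cells (2 lower), Schwann cells (2 higher), skeletal muscle (2 lower) and mast cells (1 lower). Some of these lists passed when 1 array was left out: T and NK cells without LFD replicate 1 (median 0.78, adjusted p = 0.00167), smooth muscle and pericytes without LFD replicate 2 (-0.16, 0.0238), and pancreas without LFD replicate 2 (0.58, 0.0350). So did skeletal muscle without HFD replicate 2 (0.49, 0.000117) and liver without LFD replicate 1 (-1.18, 0.0442) and without HFD replicate 2 (-0.80, 0.0133). Schwann cells passed as lower in fry (adjusted p = 0.0405) and without the filter on dim probes (0.00902). Preadipocytes and fibroblasts passed as lower with normexp (median -0.16, adjusted p = 0.0372) and without the filter (0.0188), and their median was -0.33 without LFD replicate 2 (0.0844). With the mean of each gene's probes the calls for Esr1 and Pdgfra were lost (adjusted p = 0.0792 and 0.0537) and Dlk1 had a log2 change of -0.82. The call for Irf8 was lost with quantile normalisation (0.0507), and those for Ivl, Prx and Serpinb2 with normexp (0.570, 0.398 and 0.0552). With normexp the log2 change was 1.15 for Ccl17, -0.65 for Siglech and -0.72 for Mal. Red blood cells, with 4 measured genes, were not tested as a list, and Hba-a1 had a log2 change of 0.21 (SE 0.13, adjusted p = 0.324).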

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

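All alternatives here were planned, but the rule that reads a list's sign from its median was set after the first results were seen. None of the 129 called genes named in the text changed sign in 14 settings, and none of the 16 called lists in 17; 13 of the lists kept their call in all but the estimated correlation and fry. Counts moved more than directions. Against 1019 genes higher and 995 lower, normexp gave 1611 higher, a signal well above background on all arrays 1599 higher, trend and robust options 1826 and 1808, a threshold of 0.10 gave 2260 and 2188, and a 2-fold minimum 496 and 472. Without the filter on dim probes limma called 0 higher and 0 lower, with 5608 genes at an unadjusted p under 0.05 and 13 lists lower; the prior degrees of freedom were 1.61 against 2.24. The median of all genes then shifted to 0.20. Leaving out 1 array gave 9 to 471 higher and 9 to 338 lower: 427 and 264 without LFD replicate 1, 471 and 338 without LFD replicate 2, 10 and 9 without HFD replicate 1, and 9 and 9 without HFD replicate 2. The lone array was assumed to vary like the other diet, and 12 genes were called without each array in turn. With the replicate number as a block 220 were higher and 208 lower. The numbers were not shown to pair samples: differences between replicates 1 and 2 had r = -0.00458 between diets across 26054 probes, which are not independent. With an estimated correlation camera called 0 lists higher and 0 lower, and fry 4 higher and 6 lower, 7 of them among the 16 called lists; the others were insulin signalling, mammary and other epithelium, and Schwann cells and nerve. Lists with an estimated correlation near 0, such as immediate early genes (0.023), lost their camera call like the others, so the size of the correlation alone did not decide it. Fewer degrees of freedom apply with an array left out and in camera with an estimated correlation. Apart from that, the cause of these moves was not tested.

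Among named genes and lists, sign changes were limited to those that did not pass; of all 2014 called genes, 99.6% or more of those tested kept their sign in each setting. With normexp the median was -0.013 for cholesterol synthesis and -0.065 for the hypoxia response, and Lipe was 0.017. Quantile normalisation gave 0.00226 for adipocyte identity, -0.020 for cholesterol synthesis, -0.00364 for the interferon response, -0.058 for the hypoxia response and -0.12 for dendritic cells. Scaling on the median gave 0.00354 for adipocyte identity, which was 0.097 without genes shared by lists. Without the filter mast cells had 0.014 and ovary and uterus 0.18. With all arrays well above background Schwann cells and nerve had 0.22. The mean of a gene's probes gave -0.036 for cholesterol synthesis, -0.012 for the hypoxia response, -0.21 for mammary and other epithelium and 0.013 for Krt10. Ranges from without LFD replicate 1 to without LFD replicate 2 crossed 0 for most others: -0.26 to 0.23 for cholesterol synthesis, -0.17 to 0.15 for the hypoxia response, 0.43 to -1.02 for B and plasma cells, -0.18 to 0.25 for mammary and other epithelium, 0.14 to -0.16 for smooth muscle and pericytes, -0.20 to 0.073 for adipocyte identity, 0.16 to -0.14 for the interferon response, -0.10 to 0.00156 for antioxidant defence, 0.78 to -0.46 for T and NK cells and -1.18 to 0.24 for liver. For genes they were -0.020 to 0.051 for Scd1, -0.011 to 0.74 for Fga, -0.35 to 0.062 for Lipe and -0.56 to 0.021 for Pparg. Dendritic cells had -0.25 without LFD replicate 2 and 0.22 without HFD replicate 2. From without HFD replicate 1 to without HFD replicate 2, the circadian clock had -0.36 to 0.023 and Apoa2 0.16 to -3.93. Left-out HFD arrays also turned the hypoxia response (-0.00436 without replicate 1), B and plasma cells (0.13) and liver (0.18), and, without replicate 2, cholesterol synthesis (-0.060), the interferon response (-0.074) and T and NK cells (-0.22).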

Other observations

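The tests of gene families and all tests of explanations here were chosen after the results were seen. Genes were grouped into 468 families by the letters that start their symbols; 6 were higher and 7 lower in camera, and 0 with an estimated correlation (adjusted p = 0.998). All 5 tested Ear genes, eosinophil-associated ribonucleases, were higher (median log2 change 2.44). Of 7 Mup genes, which encode major urinary proteins, 6 were lower (median -4.53). Both families hold near-identical copies that a probe may not tell apart; the medians were 2.09 and -3.97 with normexp. Insulin-like growth factor binding proteins were lower in 4 of 6 genes, Igfbp2, Igfbp3, Igfbp5 and Igfbp6 (median -0.88), and Toll-like receptors higher in 4 of 8, Tlr2, Tlr5, Tlr6 and Tlr7 (median 0.80). Olfactory receptors had a median of 0.35 over 231 genes, with 4 higher, and 0.15 without LFD replicate 1. Signal at negative control spots was also higher on the HFD arrays (97.0 and 109.5) than on the LFD arrays (63.5 and 85.9). Whether background contributed to the olfactory receptor median was not tested. The signs of these 5 families held under normexp, quantile and median scaling.

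Arrays of the same diet differed in lymphocyte and liver genes. Relative to each gene's mean, B and plasma cell genes had medians of 0.99 and -0.62 on the LFD arrays and -0.46 and 0.22 on the HFD arrays. Liver genes had -0.29 and 0.83 on the LFD arrays and -0.64 and 0.36 on the HFD arrays. T and NK cell genes had 0.43 and -0.64 on the LFD arrays and -0.31 and 0.43 on the HFD arrays.

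Some epithelial genes fell, among them 8 of 8 urothelium genes (median -2.44) picked because they had been seen to fall, while the fixed list of mammary and other epithelium did not pass. Dilution of every other cell type by adipocyte RNA is argued against by the median over endothelial, preadipocyte and smooth muscle genes, 0.017 (n = 48, SD over genes 0.63), although the preadipocyte list by itself passed as lower with normexp (-0.16). Bladder lining carried into the LFD samples may be a source: of 20 other urothelium genes 9 were lower and 0 higher in limma, with a median of -0.63 (SD over genes 1.46; camera adjusted p = 0.000505, and 0.429 with an estimated correlation), which was -0.05 with normexp, so this cannot be told apart from other epithelium, and mesothelium also expresses Krt7, Krt19, Upk1b and Upk3b. Mammary ducts also stay open, since the median of 0.26 over 15 mammary genes comes from a list without the fallen keratins. An effect of diet on these cells was not tested.

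Macrophage genes rose by a median of 1.31. A lower share of adipocytes would raise markers of every other cell type, but endothelial, preadipocyte and mesothelium genes had a median of -0.14 (n = 49, SD over genes 0.97). That pool includes mesothelium genes, which had already been seen to fall (median -1.74). By list, the median was 0.09 for endothelial cells and -0.15 for preadipocytes and fibroblasts, and neither list passed as higher. The signal of HFD replicate 2 did not account for the rise of macrophage genes, as their median without that array was 1.28. An equal increase of all kinds of macrophage found in LFD is argued against by 4 of 14 genes of alternatively activated and resident macrophages that fell, Cd163, Timd4, Ccl24 and Lyve1, the last also a marker of lymphatic endothelium. Of the same 14 genes 2 were higher, Clec10a among them, and the list did not pass (median 0.29, camera adjusted p = 0.881). Adjusted over the list alone, 4 were higher and 5 lower. A hypothesis left open is that diet changed which macrophages were present, which may include a change of expression within them.

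Tph2 and Slc5a7 rose from below background. Nerve cells in the HFD samples would raise neuron genes, by a fold that depends on their level in LFD. The median log2 change of the 12 tested was -0.23 (SD over genes 0.72), and 0.036 with normexp. All 12 were well above background on both LFD arrays, whereas Tph2 and Slc5a7 were not, so this median cannot exclude nerve cells. Nefl, Gap43, Scg2 and Elavl4, which were not well above background on either LFD array, were not on either HFD array. The median was used after a count had left the question open, with Elavl3 and Syp higher and Uchl1 lower of 20 genes on the array. A probe that also binds another transcript cannot be told apart from a true rise, because the array has 2 probes for these genes, 1 for each. Serotonin or choline handling by fat tissue on HFD may be a biological reading, but it was not tested.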
